A study of Mus musculus with 7 samples.

How the data were processed

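RNA from mouse pancreatic tumours was profiled on 7 Affymetrix whole-transcript mouse gene arrays, with biotin-labelled material from 1 sample on each array. The mice carried the KIC genotype, in which Pdx1-driven Cre recombinase switches on a mutant Kras allele and deletes Ink4a/Arf in the pancreas. The samples differed in Nupr1, a gene for a small stress-induced nuclear protein, whose exon 2 was deleted on both alleles (2 arrays, knockout), on 1 allele (2 arrays, heterozygote) or on neither (3 arrays, wild type). Genotype and replicate number were taken from the sample titles. The labels do not say whether each array came from a separate animal, so the p-values measure the spread between these samples, part of which may be technical.

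The deposited table holds log2 values for 35556 probe sets, which the authors computed with RMA, per the submitters' processing notes. No version, library file or genome build is given in the sources used here. The medians of the 7 arrays lay between 8.06 and 8.20. RMA summarises several probes per probe set after normalization between arrays, so that a change shared by most genes is removed and values of dim probe sets are compressed towards the background. The number of arrays limits the precision here.

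Probe sets were named through the platform annotation, with symbols updated through gene identifiers where the reference gene table (assembly GRCm38.p6, used for names and for the order of neighbouring genes) allowed it. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and were left out, and 12146 were not listed in that annotation and are unnamed here. Identifiers matched for 21698 probe sets. For the 999 genes with several probe sets, the probe set with the highest mean over all arrays was used. Of 19938 genes, 15610 were tested because they exceeded the 30th percentile of their array on at least 2 arrays, and 4328 were left out as dim. No column of the table was left without a sample.

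Genes were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on the log2 values. A mean was fitted for each genotype over all 7 arrays, which left 4 residual degrees of freedom (prior degrees of freedom 2.18), followed by empirical Bayes moderation with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05, two-sided. A second model used the number of intact Nupr1 alleles (0, 1 or 2) as a numeric term. In both models each gene had 1 spread, shared by all genotypes. Gene lists of cell types, pathways and complexes were fixed before the data were examined. Of 45 lists, 44 had at least 5 tested members and were tested with camera at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The list of erythroid genes had only 3 tested members and was not tested. Camera with an estimated correlation and fry were the alternatives. Fry asks whether the genes of a list move on balance in 1 direction, without setting them against other genes. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom of the fit, which it does not at the preset correlation. A call lost there can therefore come from either change. For a named gene that lay below the 30th percentile on every array of 1 genotype, a lower bound was computed as the mean of the other genotype minus that percentile, also for knockout 1 alone, and list medians were repeated with such genes at their bound (0 where both genotypes were dim or the sign changed). A list's shift is the median over its members of the log2 difference.

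The genes named in the text followed a rule also fixed before the data were examined. It takes Nupr1, and then the genes of largest rise and largest fall among those past the threshold whose arrays did not overlap between the genotypes (12 each way for knockout against wild type and 6 each way for the other comparisons and the allele model, for which last no separation was asked). Open places went to the smallest unadjusted p in that direction with separated arrays. Placeholder symbols were skipped. From each list it takes up to 4 members of the largest change in the list's direction if the list passed in knockout against wild type, up to 2 members of the largest change in either direction if it did not, and up to 3 members of lists that passed in the other comparisons. A gene named outside this rule is said to be so.

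The procedure was tested on simulated data for 15610 genes with 200 changed genes, over 10 simulations. In knockout against wild type 60.4% of genes changed by a log2 value of 1 were recovered and 93.1% of those changed by 2, with 9 false calls on average. In heterozygote against wild type the shares were 57.7% and 91.2%, and in knockout against heterozygote 49.5% and 90.2%. Genes were simulated as independent, and all arrays of a gene shared 1 spread. In the data the SD of the difference was 0.695 between the knockout arrays and 0.127 between the heterozygous arrays. The shares recovered therefore may not hold for these data. Of lists shifted by -0.5 in knockout against wild type 100% were recovered, with 0.3 false lists among 40 unshifted ones on average; those simulated genes were independent of each other, unlike real list members.

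The alternatives were no filter or a stricter filter on dim genes (50th percentile), quantile normalization or median centring of the deposited values, the mean over a gene's probe sets, empirical Bayes without the trend or with robust estimation, array weights, the replicate number as a block, fits of only the genotypes compared, an added 2-fold requirement, and leaving out each array in turn. Leaving out the 2 arrays with Y-linked signal, counting the heterozygous arrays as 1 sample, the acinar mean as a covariate and the crossed block were added after seeing the data. A tested gene or list was counted as reversed under an alternative when its direction changed and it passed the threshold in either fit. For a list this is the direction of the list test, which can differ from the sign of the median. Changes of direction with no call in either fit are counted separately.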

Results

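Expression was measured in KIC pancreatic tumours labelled as Nupr1 knockout (2 arrays), heterozygote (2 arrays) and wild type (3 arrays). The question, as the series design gives it, was how homozygous loss of Nupr1 affects the development and biology of pancreatic adenocarcinoma in this model. All values below are log2 expression or differences of log2 expression, and n is the number of arrays.

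Nupr1 was examined first, in every array. It stood at 9.38 in knockout 1, at 11.42 in the array labelled knockout 2, at 10.34 and 10.35 in the heterozygous arrays and at 11.16, 11.10 and 11.28 in the wild-type arrays. The array labelled knockout 2 was therefore not below wild type, which goes against its label. Whether the probes of this probe set lie in the deleted exon 2 is not given in the sources used here, so a signal from the remaining exons cannot be told from an intact gene. The difference between knockout and wild type was -0.78 ± 0.54 (SE; limma adjusted p = 0.42). Without the array labelled knockout 2 it was -1.80 (limma adjusted p = 0.042), and without knockout 1 it was 0.235; over 20 alternatives the adjusted p ran from 0.014 to 0.77. Heterozygotes differed from wild type by -0.84 ± 0.54 (SE; limma adjusted p = 0.60), which passed in 5 of 20 alternatives. The fit pools the spread over all genotypes, and the knockout arrays lay 2.03 apart. Both heterozygous arrays lay below all wild-type arrays, so this SE and p do not measure the spread within those 2 groups. Knockout and heterozygote differed by 0.06 (limma adjusted p = 0.96), which passed in 2 of 21 alternatives, upwards without knockout 1 (1.07) and downwards without both arrays with Y-linked signal (-0.96). Every direction given below for the knockout rests in part on the array labelled knockout 2.

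**Figure D1:**
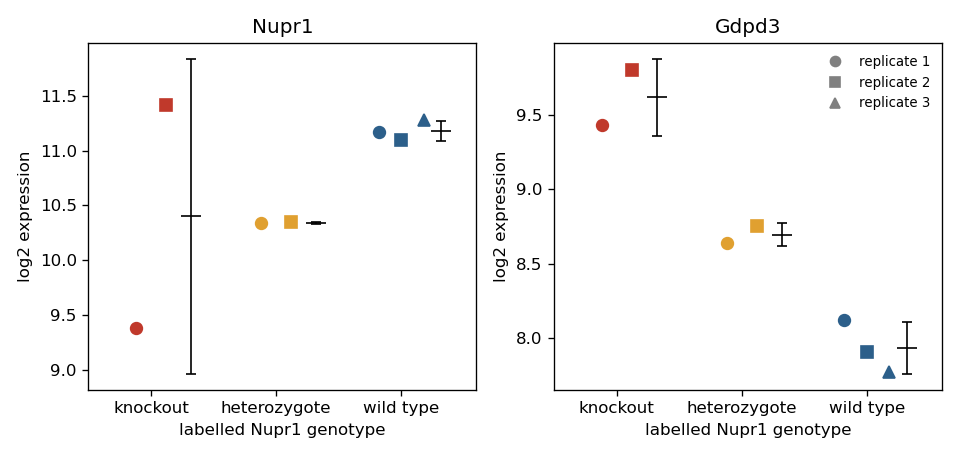
Log2 expression of Nupr1 (left) and of Gdpd3 (right), a gene close to Nupr1 on chromosome 7, for each array by labelled genotype; symbols show the replicate number, and black bars the mean ± SD of the 2 or 3 arrays. The array labelled knockout 2 has a Nupr1 value of 11.42, above the 3 wild-type arrays, while its Gdpd3 value of 9.80 lies beside that of knockout 1 at 9.43.

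The arrays differed in more than genotype. Across the tested genes the array labelled knockout 2 correlated with the others at 0.82 to 0.87, while the lowest correlation among the other 6 arrays was 0.92; these correlations are across genes, which are not independent replicates. It held high levels of digestive enzyme and endocrine transcripts, with the elastase gene Cela1 at 13.80 against 8.07 to 8.97 on the other arrays, the acinar transcription factor gene Ptf1a (dim and not tested) at 10.80 against 6.76 to 7.01, and glucagon (Gcg) at 13.07 against 6.97 to 11.79. The heterozygous arrays were nearly alike, with a correlation of 0.996 and 19 genes that differed more than 2-fold, against 151 or more for other pairs of the same genotype. Eif2s3y, a Y-linked gene, stood at 9.30 in the array labelled knockout 2 and at 9.59 in wild type 1 and at 4.80 to 4.94 on the others, and the same 2 arrays had low Xist (6.42 and 6.67 against 12.82 to 13.06). Sex is not given in the labels, but read from these genes the 2 arrays came from males and the others from females. Sex was thus not balanced over the genotypes, as both heterozygous arrays were on the female side. Cela1, Ptf1a, Gcg, Eif2s3y and Xist were chosen here after their values were seen.

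In the comparison of knockout with wild type, genes of cell division, macrophages and activated stroma were lower in the knockout arrays, and acinar and epithelial junction genes were higher, as groups in camera. None of these lists was called with an estimated correlation (adjusted p = 0.26 to 0.71), and islet genes were higher in the array labelled knockout 2 (median 1.94) but not in knockout 1 (-0.17). The myeloid membrane protein gene Ms4a6c stood at 10.03 ± 0.01 in knockout and 11.53 ± 0.11 in wild type, and the spindle checkpoint kinase gene Bub1 at 7.69 ± 0.35 and 9.30 ± 0.31 (mean ± SD, n = 2 and 3). Albumin (Alb), the main plasma protein of the liver, stood at 9.46 ± 0.13 and 6.86 ± 0.35. Single genes were less clear, and no gene of 15610 passed an adjusted p of 0.05 in limma (smallest adjusted p = 0.052). An unadjusted p under 0.05 was reached by 3055 genes, 1208 higher and 1847 lower, where 780 are expected by chance. At an adjusted p of 0.10, 84 genes would be called. With only knockout and wild type fitted, without the heterozygous arrays, the smallest limma adjusted p was 0.30. In that fit 1929 genes had an unadjusted p under 0.05. The smallest limma adjusted p was 0.25 with the replicate number as a block and 0.51 with array weights. Without knockout 1, 5478 genes were called, and without the array labelled knockout 2, 17 were. The fit without the variance trend called 2 genes, quantile normalization called 6 (1 higher and 5 lower) and median centring 8 (1 higher and 7 lower).

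None of the single genes named next passed the threshold. Among those of smallest p with separated arrays, Ms4a6c and Ms4a6d, membrane proteins of myeloid cells, differed by -1.500 ± 0.11 and -1.79 ± 0.14 (SE, n = 2 and 3; limma adjusted p = 0.052 for both). A2m, a protease inhibitor, differed by -1.71 and Hgf, the ligand of the Met receptor, by -1.33. The Wnt inhibitor Wif1 differed by -1.94 and the matrix protein Thbs4 by -2.23. Col6a3 differed by -0.97, the proteoglycan gene Vcan by -1.16 and Dad1 by -0.88. Casp1, the inflammatory caspase, Tlr6 and Gpr141 lay below the 30th percentile on both knockout arrays and, set against it, were lower by at least 1.47, 0.07 and 0.55. In the other direction, albumin (Alb) differed by 2.604 ± 0.21 (SE, limma adjusted p = 0.052), Gdpd3 by 1.68 ± 0.16, Scarna17 by 0.99, Syt9 by 1.03, Thsd4 by 0.92, Cdc42bpg by 0.90, Th by 0.75, Serpind1 by 0.76, Tmem63c (dim on all wild-type arrays) by at least 0.59, Fam149a by 0.80, Mturn by 0.79 and Cys1 by 0.63. Their limma adjusted p lay between 0.052 and 0.105.

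Of the 44 lists, 18 shifted between knockout and wild type in camera, 8 upwards and 10 downwards. None of them was called with an estimated correlation (adjusted p = 0.26 to 0.99 over the 44 lists with an estimated correlation). This alone does not show that correlation between genes accounts for the shifts. The estimated correlation was 0.78 for mitosis, but 0.016 for matrix collagens and proteoglycans, near the preset 0.01. The unadjusted camera p of that collagen list still went from 2.2e-08 to 0.0059. Fry called 5, namely activated myofibroblasts, macrophages, matrix collagens and proteoglycans, matrix metalloproteinases and inhibitors, and smooth muscle and pericytes.

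Cell division genes were lower, and the mitosis list had the smallest p in camera at the preset correlation, though fry did not call it (adjusted p = 0.058). All 31 tested genes of the mitosis list were lower in the knockout, with a median of -0.88 (camera adjusted p = 6.7e-17, and adjusted p = 0.58 with an estimated correlation), and 28 of the 31 were lower adjusted over the list alone, though 0 over all genes tested. Bub1, a spindle checkpoint kinase, differed by -1.61 ± 0.23 and Cenpe, a kinetochore motor, by -1.16, while Hmmr and Nuf2, a kinetochore component, were dim on both knockout arrays and lower by at least 1.06 and 1.16. The median of this list was -0.67 in knockout 1 and -1.05 in the array labelled knockout 2, relative to the wild-type mean. The DNA replication and S phase list had a median of -0.42 (camera adjusted p = 6.1e-07, and adjusted p = 0.61 with an estimated correlation), and 5 of 26 members were lower adjusted over the list alone, with Rrm1 at -0.97, Pole at -0.83, Rfc4 at -0.73 and Mcm6 at -0.70. DNA replication and S phase stood at a median of -0.19 without the array labelled knockout 2.

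Stromal lists were lower as well. Activated myofibroblasts had a median of -0.90 (camera adjusted p = 4.8e-08, and adjusted p = 0.47 with an estimated correlation) with 13 of 16 members lower adjusted over the list alone. Inhba differed by -1.59, tenascin C (Tnc) by -1.34, Cnn1 by -1.21 and Thbs2 by -1.12. Matrix collagens and proteoglycans had a median of -0.65 (camera adjusted p = 2.0e-07, and adjusted p = 0.26 with an estimated correlation) with 9 of 19 lower adjusted over the list alone. Beside Vcan and Col6a3, given above, Col12a1 stood at -1.52 and Col8a1 at -0.95. Fibroblast genes had a median of -0.49 (camera adjusted p = 0.0028, and adjusted p = 0.49 with an estimated correlation) with 7 of 19 lower adjusted over the list alone, and Thy1, Pdgfrb, Sfrp1 and Lum differed by -1.28, -1.01, -0.998 and -0.94. Smooth muscle and pericyte genes had a median of -0.60 (camera adjusted p = 5.3e-04, and adjusted p = 0.34 with an estimated correlation) with 6 of 14 lower adjusted over the list alone. Actg2, Des, Kcnj8 and Cspg4 differed by -1.67, -1.19, -0.86 and -0.76. Mesenchymal transition genes had a median of -0.56 (camera adjusted p = 7.5e-05, and adjusted p = 0.61 with an estimated correlation) with 6 of 17 lower adjusted over the list alone. Prrx1, S100a4, Tgfbi and Itga5 differed by -1.51, -1.17, -1.13 and -1.07. Matrix metalloproteinases and inhibitors had a median of -0.65 (camera adjusted p = 1.0e-04, and adjusted p = 0.35 with an estimated correlation) with 4 of 18 lower adjusted over the list alone. Mmp12, Mmp10, Adamts12 and Adamts4 differed by -1.17, -1.05, -0.91 and -0.82. Leaving out 1 array moved medians by over 1.5 times or ended the call as follows. Activated myofibroblasts stood at -0.56 without the array labelled knockout 2. Fibroblasts stood at 0.03 without knockout 1 (not called) and -0.77 without the array labelled knockout 2. Smooth muscle and pericytes stood at -0.65 without knockout 1 (not called). Mesenchymal transition stood at -0.89 without knockout 1 and -0.31 without the array labelled knockout 2.

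Among immune genes, all 21 macrophage markers were lower, with a median of -0.75 (camera adjusted p = 6.7e-08, and adjusted p = 0.35 with an estimated correlation), and 9 were lower adjusted over the list alone. Msr1, a scavenger receptor, differed by -1.56 ± 0.22, the C-type lectin gene Clec4n by -1.54, the myeloid transcription factor Spi1 by -1.08 and Fcgr1 by -1.07. B and plasma cell genes had a median of -0.89 (camera adjusted p = 0.022, and adjusted p = 0.84 with an estimated correlation) but 0 of 15 were called adjusted over the list alone. Ighm stood at -1.05, and Ms4a1, Fcer2a and Cd79a, dim on both knockout arrays, were lower by at least 0.71, 0.65 and 0.73. With dim genes at their bound the list median was -0.71 here and -0.85 for mitosis. The wild-type arrays themselves ranged from -1.18 to 0.72 on the B and plasma cell list. On leaving out 1 array, medians moved as follows. Macrophages stood at -0.45 without knockout 1. B and plasma cells stood at -1.10 without knockout 1 (not called), -0.71 without the array labelled knockout 2 (not called), -1.52 without wild type 1, -0.61 without wild type 2 (not called) and -0.45 without wild type 3 (not called).

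Several of the higher lists were carried by the array labelled knockout 2, and acinar genes were highest there. All 25 acinar genes were higher, with a median of 2.22 (camera adjusted p = 3.1e-08, and adjusted p = 0.66 with an estimated correlation) and 0 called adjusted over the list alone. Ctrc, Spink1, Pnliprp2 and Cela2a stood at 3.43, 3.28, 3.24 and 3.17. The list median was 1.09 in knockout 1, 3.39 in the array labelled knockout 2 and between -1.28 and 0.65 in the wild-type arrays. Islet genes had 18 of 18 members higher, 0 of them called adjusted over the list alone, and a median of 0.81 (camera adjusted p = 5.3e-04, and adjusted p = 0.84 with an estimated correlation). The values of Slc30a8, Scg3, Iapp and Pcsk1 were 1.58, 1.495, 1.30 and 1.26. Mesothelial genes had 9 of 11 members higher, 0 of them called adjusted over the list alone, and a median of 0.50 (camera adjusted p = 0.032, and adjusted p = 0.65 with an estimated correlation). The values of Upk1b, Lrrn4, Upk3b and Nkain4 were 1.40, 1.24, 1.08 and 0.95. Endoplasmic reticulum chaperones and unfolded protein response genes had 19 of 24 members higher, 0 of them called adjusted over the list alone, and a median of 0.27 (camera adjusted p = 0.022, and adjusted p = 0.84 with an estimated correlation). The values of Derl3, Sec61b, Herpud1 and Sel1l were 1.25, 0.77, 0.71 and 0.67. ATF4 and CHOP targets had 22 of 26 members higher, 0 of them called adjusted over the list alone, and a median of 0.34 (camera adjusted p = 1.3e-04, and adjusted p = 0.58 with an estimated correlation). The values of Aldh1l2, Slc7a3, Chac1 and Mthfd2 were 1.65, 1.34, 1.21 and 1.01. On leaving out 1 array, medians moved as follows. Acinar cells stood at 3.39 without knockout 1 and 1.09 without the array labelled knockout 2. Islet endocrine cells stood at 1.94 without knockout 1, -0.17 without the array labelled knockout 2 (not called), 0.53 without wild type 1 and 1.24 without wild type 3. Mesothelial cells stood at 1.33 without knockout 1, -0.0024 without the array labelled knockout 2 (not called) and 0.40 without wild type 1 (not called). Endoplasmic reticulum chaperones and unfolded protein response stood at 0.63 without knockout 1, -0.10 without the array labelled knockout 2 (called in the other direction) and 0.26 without wild type 1 (not called). ATF4 and CHOP targets stood at 0.61 without knockout 1 and 0.09 without the array labelled knockout 2 (not called).

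Epithelial junction genes were higher in both knockout arrays. All 20 members lay above the wild-type mean, with a median of 0.67 (camera adjusted p = 1.8e-05, and adjusted p = 0.71 with an estimated correlation) and 1 called adjusted over the list alone. Prss8, Crb3, Cldn7 and Esrp2 stood at 1.41, 1.07, 1.00 and 0.89. The list median was 0.63 in knockout 1, 0.72 in the array labelled knockout 2, and -0.78, 0.25 and 0.52 in the wild-type arrays. Ribosomal protein genes had 18 of 21 members higher, 0 of them called adjusted over the list alone, and a median of 0.13 (camera adjusted p = 0.0036, and adjusted p = 0.84 with an estimated correlation). The values of Rps14, Rpl24, Rpl13 and Rpl22 were 0.90, 0.45, 0.38 and 0.32. Hepatocyte genes had 8 of 10 members higher, and a median of 0.38 (camera adjusted p = 0.013, and adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 1 member passed upwards and 1 downwards. Beside Alb, given above, Ttr, Ambp and Apob differed by 1.29, 1.20 and 0.56. On leaving out 1 array, medians moved as follows. Epithelial junctions stood at 0.32 without wild type 1. Ribosomal proteins stood at 0.23 without knockout 1 and 0.02 without the array labelled knockout 2 (not called). Hepatocytes stood at 0.11 without knockout 1 (not called), 0.58 without the array labelled knockout 2 and 0.33 without wild type 1 (not called).

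The other 26 lists did not pass in knockout against wild type, with camera adjusted p from 0.070 to 0.98. The median shift was 0.05 for ductal cells (Cldn3 1.10, Muc1 1.08) and -0.19 for acinar-to-ductal metaplasia and PanIN lesions (Reg3a 3.07, Reg3g 2.44). For inflammatory fibroblast genes it was -0.34 (Has2 -1.77, Il6 at least 0.47 lower), and for neutrophils it was 0.39 (Ngp 1.49, Trem1 -1.48). It was -0.52 for T and NK cells (Il7r -1.54, Cd3g at least 0.55 lower) and -0.20 for dendritic cells and MHC class II (Itgax -1.55, Ccr7 -0.94). For mast cells it was -0.13 (Cpa3 -0.89, Tpsab1 -0.67), and for endothelial cells it was 0.05 (Cdh5 -0.64, Sox17 0.58). It was 0.18 for adipocytes (Lpl 0.63, Pparg -0.57) and 0.05 for Schwann and nerve cells (Ncam1 -0.93, Erbb3 0.71). For intestinal epithelium it was 0.04 (Muc2 -1.32, Reg4 at least 0.70 lower), and for MAPK feedback and output it was -0.30 (Ereg -1.09, Fosl1 -0.87). It was -0.11 for p53 targets (Plk3 -0.60, Perp 0.59) and -0.17 for senescence and cell cycle inhibitors (Cdkn2b -0.89, Plaur -0.89). For NF-kB targets it was -0.27 (Il1a -1.12, Cxcl10 -0.91), and for type I interferon response it was -0.11 (Rsad2 0.52, Oas1a -0.43). It was -0.19 for immediate early genes (Egr2 -1.12, Dusp1 -0.82) and -0.11 for hypoxia and glycolysis (Adm 0.81, Ndrg1 0.81). For oxidative phosphorylation it was -0.02 (Cox4i1 0.38, Ndufs1 -0.33), and for cholesterol and fatty acid synthesis it was -0.10 (Cyp51 -0.67, Insig1 0.56). It was -0.11 for autophagy and lysosome (Ctsb -0.43, Vmp1 -0.41) and -0.24 for apoptosis (Casp1 at least 1.47 lower, Casp12 -0.88). For NRF2 antioxidant genes it was -0.13 (Gstm1 0.75, Akr1b8 -0.66), and for Hedgehog, Notch and Wnt targets it was -0.0027 (Lef1 -1.06, Rnf43 0.85). It was -0.19 for genes that earlier work ties to Nupr1 (Cops5 -0.76, Aurka -0.49) and -0.17 for genes next to Nupr1 on chromosome 7 (Il4ra -0.52, Il21r -0.51). The camera direction differed from the sign of the median for p53 targets and for Hedgehog, Notch and Wnt targets. It differed from the sign of the mean for those lists and for intestinal epithelium, Schwann and nerve cells, oxidative phosphorylation, and metaplasia and PanIN lesions. For genes given as at least a value, all arrays of 1 genotype lay below the 30th percentile; they were picked by the measured difference, which is not exact.

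On leaving out 1 array, the medians that moved by over 0.25 or gained a call were as follows, several with opposite signs without 1 or the other knockout array. Ductal cells stood at -0.43 without knockout 1, 0.68 without the array labelled knockout 2 (called) and 0.27 without wild type 3 (called). Acinar-to-ductal metaplasia and PanIN lesions stood at -0.69 without knockout 1 and 0.35 without the array labelled knockout 2. Inflammatory fibroblast genes stood at 0.16 without knockout 1 and -0.73 without the array labelled knockout 2 (called). Neutrophils stood at 1.02 without knockout 1 (called), -0.19 without the array labelled knockout 2 and 0.08 without wild type 1. T and NK cells stood at -0.63 without the array labelled knockout 2 (called), -0.95 without wild type 1 (called) and -0.19 without wild type 3. Dendritic cells and MHC class II stood at 0.14 without knockout 1, -0.54 without the array labelled knockout 2 (called), -0.55 without wild type 1 (called) and 0.11 without wild type 3. Mast cells stood at -0.24 without wild type 1 (called). Endothelial cells stood at 0.39 without knockout 1 and -0.33 without the array labelled knockout 2. Adipocytes stood at 0.22 without wild type 3 (called). Intestinal epithelium stood at 0.19 without wild type 2 (called). MAPK feedback and output stood at -0.97 without knockout 1 (called) and 0.31 without the array labelled knockout 2 (called). Senescence and cell cycle inhibitors stood at 0.10 without the array labelled knockout 2. NF-kB targets stood at 0.03 without the array labelled knockout 2 and -0.40 without wild type 1 (called). Type I interferon response stood at 0.12 without knockout 1 (called) and -0.40 without the array labelled knockout 2 (called). Hypoxia and glycolysis stood at -0.46 without knockout 1 and 0.20 without the array labelled knockout 2 (called). Oxidative phosphorylation stood at -0.15 without the array labelled knockout 2 (called). Autophagy and lysosome stood at -0.09 without the array labelled knockout 2 (called). Apoptosis stood at -0.55 without knockout 1 (called) and 0.04 without the array labelled knockout 2. NRF2 antioxidant genes stood at -0.40 without knockout 1.

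**Figure D2:**
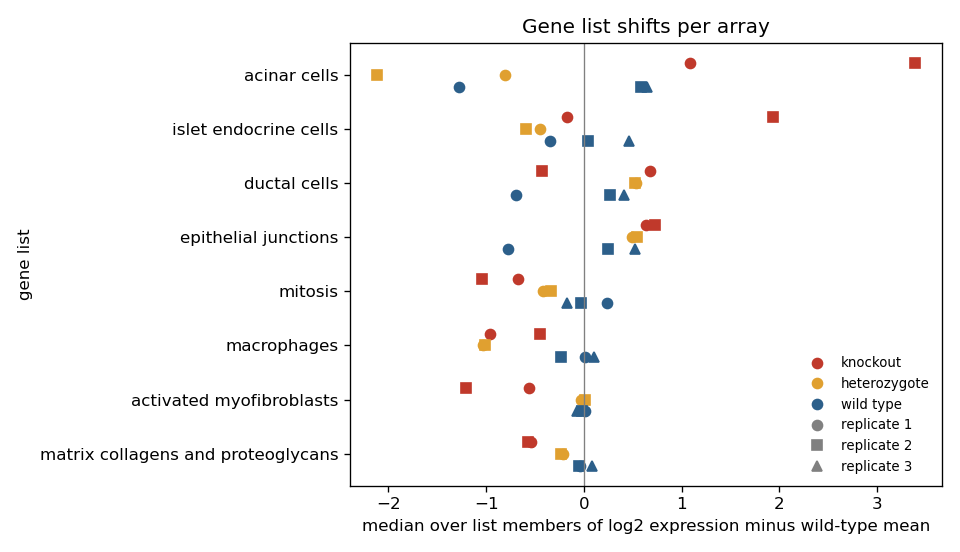
Median shift of 8 gene lists in each array, as log2 expression minus the wild-type mean over the list's members (horizontal axis); colours show the labelled genotype and symbols the replicate number. The array labelled knockout 2 lies far to the right for acinar (3.39) and islet (1.94) genes, and both knockout arrays lie to the left for mitosis, activated myofibroblasts and matrix collagens.

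In heterozygotes against wild type, macrophage, lymphocyte and cell division genes were lower as groups in camera, and junction and intestinal genes were higher. None of these lists was called with an estimated correlation (adjusted p = 0.36 to 0.72). Aqp3, an aquaporin, rose by 2.82 ± 0.21 (SE, n = 2 and 3), the intestinal alkaline phosphatase gene Alpi by 2.11 and Nptx2 by 1.30 (limma adjusted p = 0.022 to 0.048). Prl8a9, a prolactin family gene, the defensin gene Defa24 and the calpain gene Capn11 also passed (limma adjusted p = 0.0058 to 0.022), but lay below the 30th percentile on every wild-type array. Set against that percentile, they were higher by at least 1.48, 0.26 and 0.86. Cxcl13, the B cell chemokine, fell by 2.31 ± 0.17, Arhgap15 by 2.21, Dock10 by 2.00, Emb by 1.83, Tom1l2 by 1.79 and the integrin gene Itga4 by 1.65 (limma adjusted p = 0.022 to 0.049). In all, 19 of 15610 genes passed in limma, 6 higher and 13 lower, with 1945 at an unadjusted p under 0.05. With the heterozygous arrays counted as 1 sample, or with either of them left out, 0 genes were called. Without the array labelled knockout 2, 582 were, and without knockout 1, 596. Without wild type 2 the count was 29 and without wild type 3 it was 2. Leaving out 1 knockout array also removes the spread between the knockout arrays from the pooled estimate.

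Of the 44 lists, 20 shifted between heterozygotes and wild type in camera, 6 upwards and 14 downwards. None was called with an estimated correlation (adjusted p = 0.36 to 0.995). Fry called macrophages only. For macrophages, 21 of 21 members were lower, with a median of -1.02 (camera adjusted p = 4.3e-16, and adjusted p = 0.36 with an estimated correlation). Adgre1 -1.80, Spi1 -1.73 and Clec4n -1.41 were the largest values, and 17 passed adjusted over the list alone. Mitosis had 31 of 31 members lower and a median of -0.38 (camera adjusted p = 4.0e-09, and adjusted p = 0.72 with an estimated correlation), with Kif11 -0.92, Nuf2 -0.77 and Hmmr -0.73 and 6 called adjusted over the list alone. The median was -0.60 for fibroblasts (camera adjusted p = 3.3e-05, and adjusted p = 0.53 with an estimated correlation), where 17 of 19 members were lower and 4 passed adjusted over the list alone. Dpt -2.34, Pi16 -1.58 and Fap -1.46 were its largest values. For T and NK cells, 14 of 14 members were lower, with a median of -0.87 (camera adjusted p = 1.0e-04, and adjusted p = 0.72 with an estimated correlation). Il7r at least 1.67 lower, Cd3g at least 0.52 lower and Cd4 -1.28 were the largest values, and 0 passed adjusted over the list alone. B and plasma cells had 14 of 15 members lower and a median of -1.18 (camera adjusted p = 1.0e-04, and adjusted p = 0.72 with an estimated correlation), with Ms4a1 at least 0.68 lower, Jchain -1.92 and Cd79a at least 0.71 lower and 0 called adjusted over the list alone. The median was -0.74 for dendritic cells and MHC class II (camera adjusted p = 1.2e-04, and adjusted p = 0.72 with an estimated correlation), where 13 of 13 members were lower and 0 passed adjusted over the list alone. Cd209a at least 1.51 lower, Itgax -1.44 and H2-DMa -1.13 were its largest values. For acinar cells, 23 of 25 members were lower, with a median of -1.49 (camera adjusted p = 4.8e-04, and adjusted p = 0.72 with an estimated correlation). Pnliprp1 -3.14, Cel -2.72 and Gp2 -2.58 were the largest values, and 0 passed adjusted over the list alone. Endothelial cells had 16 of 18 members lower and a median of -0.54 (camera adjusted p = 0.003, and adjusted p = 0.72 with an estimated correlation), with Emcn -1.06, Cdh5 -0.96 and Tek -0.86 and 0 called adjusted over the list alone. The median was -0.72 for neutrophils (camera adjusted p = 0.0032, and adjusted p = 0.72 with an estimated correlation), where 14 of 16 members were lower and 3 passed adjusted over the list alone. Retnlg at least 1.16 lower, Mmp8 -1.73 and Ngp at least 0.95 lower were its largest values. For DNA replication and S phase, 21 of 26 members were lower, with a median of -0.17 (camera adjusted p = 0.0032, and adjusted p = 0.72 with an estimated correlation). Prim1 -0.70, Rrm1 -0.55 and Rfc4 -0.44 were the largest values, and 1 passed adjusted over the list alone. Matrix metalloproteinases and inhibitors had 14 of 18 members lower and a median of -0.27 (camera adjusted p = 0.0037, and adjusted p = 0.72 with an estimated correlation), with Mmp8 -1.73, Adamts5 -1.51 and Mmp12 -1.28 and 2 called adjusted over the list alone. The median was -0.30 for type I interferon response (camera adjusted p = 0.0054, and adjusted p = 0.72 with an estimated correlation), where 18 of 20 members were lower and 0 passed adjusted over the list alone. Oas2 -1.01, Oasl2 -0.92 and Ddx60 at least 0.30 lower were its largest values. For NF-kB targets, 16 of 20 members were lower, with a median of -0.27 (camera adjusted p = 0.0065, and adjusted p = 0.72 with an estimated correlation). Rel -0.92, Birc3 -0.81 and Traf1 -0.77 were the largest values, and 2 passed adjusted over the list alone. Matrix collagens and proteoglycans had 15 of 19 members lower and a median of -0.22 (camera adjusted p = 0.0066, and adjusted p = 0.66 with an estimated correlation), with Ogn at least 1.70 lower, Aspn -1.20 and Eln -1.19 and 2 called adjusted over the list alone. The medians that moved by over 1.5 times, or lost their call, when 1 array was left out follow. Mitosis stood at -0.24 without wild type 1. T and NK cells stood at -1.31 without wild type 1 and -0.54 without wild type 3. B and plasma cells stood at -0.76 without wild type 3. Dendritic cells and MHC class II stood at -0.43 without wild type 3. Acinar cells stood at -0.81 without heterozygote 2. Endothelial cells stood at -0.35 without wild type 3. Neutrophils stood at -0.33 without wild type 3. Type I interferon response stood at -0.45 without wild type 1, -0.32 without wild type 2 (not called) and -0.18 without wild type 3 (not called). NF-kB targets stood at -0.49 without wild type 1 and -0.08 without wild type 3 (not called). One wild-type array lay at the heterozygous level in several of these lists. Relative to the wild-type mean, wild type 1 stood at -0.86 for T and NK cells, -1.18 for B and plasma cells, -0.66 for dendritic cells and MHC class II, -0.44 for endothelial cells and -1.28 for acinar cells. The heterozygous arrays stood at -0.82 and -0.92, -1.18 and -1.23, -0.70 and -0.79, -0.52 and -0.55, and -0.81 and -2.12.

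The lists that shifted upwards in heterozygotes were the following. For epithelial junctions, 20 of 20 members were higher, with a median of 0.52 (camera adjusted p = 1.3e-04, and adjusted p = 0.72 with an estimated correlation). Cldn7 1.08, Dsc2 0.89 and Dsg2 0.89 were the largest values, and 0 passed adjusted over the list alone. Intestinal epithelium had 13 of 14 members higher and a median of 0.60 (camera adjusted p = 3.2e-04, and adjusted p = 0.72 with an estimated correlation), with Muc2 2.62, Alpi 2.11 and Reg4 1.27 and 2 called adjusted over the list alone. The median was 0.34 for hypoxia and glycolysis (camera adjusted p = 0.003, and adjusted p = 0.72 with an estimated correlation), where 21 of 26 members were higher and 0 passed adjusted over the list alone. Car9 1.05, Vegfa 0.77 and Hk2 0.76 were its largest values. For MAPK feedback and output, 16 of 19 members were higher, with a median of 0.55 (camera adjusted p = 0.016, and adjusted p = 0.77 with an estimated correlation). Spry2 1.27, Ereg 1.02 and Hbegf 1.00 were the largest values, and 0 passed adjusted over the list alone. Cholesterol and fatty acid synthesis had 19 of 22 members higher and a median of 0.25 (camera adjusted p = 0.026, and adjusted p = 0.72 with an estimated correlation), with Sqle 0.49, Hmgcs1 0.46 and Srebf2 0.42 and 0 called adjusted over the list alone. The median was 0.51 for ductal cells (camera adjusted p = 0.034, and adjusted p = 0.72 with an estimated correlation), where 13 of 16 members were higher and 0 passed adjusted over the list alone. Cftr 1.09, Tspan8 0.93 and Cldn4 0.81 were its largest values. Muc2 (11.47) and Reg4 (9.75) in wild type 2 lay above both heterozygous arrays (Muc2 11.37 and 11.41, Reg4 8.92 and 9.10). Over 20 alternatives Muc2 ran from 1.10 to 3.97 and Reg4 from 0.15 to 2.28. The medians that moved by over 1.5 times, or lost their call, when 1 array was left out follow. Epithelial junctions stood at 0.21 without wild type 1. Hypoxia and glycolysis stood at 0.16 without wild type 3. MAPK feedback and output stood at 0.37 without wild type 3 (not called). Cholesterol and fatty acid synthesis stood at 0.21 without heterozygote 2 (not called) and 0.17 without wild type 1 (not called). Ductal cells stood at 0.27 without wild type 1 (not called). Genes given as at least a value in this comparison lay below the 30th percentile on both heterozygous arrays; they were picked and ordered by the measured difference. With dim genes at their bound the median was -0.48 for fibroblasts, -0.48 for neutrophils, -0.60 for T and NK cells and -0.68 for B and plasma cells.

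In knockout against heterozygote, acinar genes were higher and myofibroblast, collagen and mitosis genes lower, as groups in camera. None of these lists was called with an estimated correlation (adjusted p = 0.67), and many of the shifts below were carried by the array labelled knockout 2. Prl8a9 (limma adjusted p = 0.0069) and Capn11 (limma adjusted p = 0.042) were lower, and both knockout arrays lay below the 30th percentile for them. Set against that percentile, they were lower by at least 1.47 and 0.85. Both were also higher in heterozygotes than in wild type, and dim on all knockout and wild-type arrays. These 2 were the only ones of 15610 genes to pass in limma, with 2071 at an unadjusted p under 0.05, and median centring gave 2 higher and 3 lower. Defa24 (at least 0.24 lower), Aqp3 (-2.73), Wif1 (-2.41) and Alpi (-2.38) on the lower side, and Alb (at least 2.39 higher), Tom1l2 (2.17), Itgbl1 (1.06), Acpp (0.97), Syt9 (1.07) and Cxcl13 (1.32) on the higher side, did not pass. Without either heterozygous array, without the array labelled knockout 2, and with the heterozygous arrays as 1 sample, 0 genes were called; without knockout 1, 5712 were.

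Of the 44 lists, 22 shifted between knockout and heterozygote in camera, 11 upwards and 11 downwards. None was called with an estimated correlation (adjusted p = 0.67 to 0.97), and fry called smooth muscle and pericytes and matrix collagens and proteoglycans. For acinar cells, 25 of 25 members were higher, with a median of 3.92 (camera adjusted p = 2.9e-14, and adjusted p = 0.67 with an estimated correlation). Pnliprp1 5.32, Cela3b 5.07 and Gp2 4.80 were the largest values, and 18 passed adjusted over the list alone. Islet endocrine cells had 17 of 18 members higher and a median of 1.55 (camera adjusted p = 1.2e-05, and adjusted p = 0.67 with an estimated correlation), with Iapp 3.57, Gcg 3.45 and Chga 2.63 and 0 called adjusted over the list alone. The median was 0.94 for neutrophils (camera adjusted p = 7.8e-04, and adjusted p = 0.67 with an estimated correlation), where 14 of 16 members were higher and 1 passed adjusted over the list alone. Ngp at least 2.44 higher, S100a8 at least 1.81 higher and Retnlg at least 1.56 higher were its largest values. For chaperones of the endoplasmic reticulum and unfolded protein response, 21 of 24 members were higher, with a median of 0.34 (camera adjusted p = 0.0018, and adjusted p = 0.67 with an estimated correlation). Derl3 2.46, Sel1l 1.21 and Herpud1 1.12 were the largest values, and 0 passed adjusted over the list alone. Endothelial cells had 16 of 18 members higher and a median of 0.59 (camera adjusted p = 0.004, and adjusted p = 0.67 with an estimated correlation), with Tek 1.11, Plvap 0.91 and Esam 0.76 and 0 called adjusted over the list alone. The median was 0.49 for dendritic cells and MHC class II (camera adjusted p = 0.0085, and adjusted p = 0.67 with an estimated correlation), where 12 of 13 members were higher and 0 passed adjusted over the list alone. Cd209a at least 1.09 higher, H2-Ab1 0.78 and Cd74 0.67 were its largest values. For ATF4 and CHOP targets, 20 of 26 members were higher, with a median of 0.33 (camera adjusted p = 0.0097, and adjusted p = 0.67 with an estimated correlation). Aldh1l2 2.01, Mthfd2 1.46 and Asns 1.28 were the largest values, and 0 passed adjusted over the list alone. Type I interferon response had 16 of 20 members higher and a median of 0.22 (camera adjusted p = 0.02, and adjusted p = 0.76 with an estimated correlation), with Oasl2 1.13, Oas2 1.05 and Rsad2 at least 0.72 higher and 0 called adjusted over the list alone. The median was 0.22 for adipocytes (camera adjusted p = 0.02, and adjusted p = 0.67 with an estimated correlation), where 10 of 13 members were higher and 0 passed adjusted over the list alone. Car3 at least 1.76 higher, Fabp4 1.64 and Lpl 1.48 were its largest values. For macrophages, 16 of 21 members were higher, with a median of 0.25 (camera adjusted p = 0.027, and adjusted p = 0.67 with an estimated correlation). Adgre1 0.96, Spi1 0.65 and Lyz2 0.65 were the largest values, and 0 passed adjusted over the list alone. Hepatocytes had 6 of 10 members higher and a median of 0.49 (camera adjusted p = 0.028, and adjusted p = 0.67 with an estimated correlation), with Alb at least 2.39 higher, Ambp 1.34 and Ttr 1.32 and 1 called adjusted over the list alone. The medians that moved by over 1.5 times, or lost their call, when 1 array was left out follow. Islet endocrine cells stood at 2.68 without knockout 1 and 0.31 without the array labelled knockout 2 (not called). Neutrophils stood at 1.40 without knockout 1 and 0.31 without the array labelled knockout 2. Endoplasmic reticulum chaperones and unfolded protein response stood at 0.75 without knockout 1 and 0.03 without the array labelled knockout 2 (not called). Endothelial cells stood at 0.24 without the array labelled knockout 2 (not called). Dendritic cells and MHC class II stood at 0.76 without knockout 1 and 0.23 without the array labelled knockout 2 (not called). ATF4 and CHOP targets stood at 0.60 without knockout 1 and 0.05 without the array labelled knockout 2 (not called). Type I interferon response stood at 0.42 without knockout 1 and 0.08 without the array labelled knockout 2 (not called). Adipocytes stood at 0.18 without knockout 1 (not called). Macrophages stood at 0.46 without knockout 1 and 0.10 without the array labelled knockout 2 (not called). Hepatocytes stood at 0.33 without knockout 1 (not called).

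The lists that shifted downwards in the knockout against heterozygote were the following. For mitosis, 31 of 31 members were lower, with a median of -0.46 (camera adjusted p = 3.6e-07, and adjusted p = 0.67 with an estimated correlation). Bub1 -1.01, Cenpe -0.77 and Prc1 -0.73 were the largest values, and 0 passed adjusted over the list alone. Activated myofibroblasts had 15 of 16 members lower and a median of -0.87 (camera adjusted p = 4.2e-07, and adjusted p = 0.67 with an estimated correlation), with Inhba -2.17, Cnn1 -2.11 and Tnc -1.58 and 9 called adjusted over the list alone. The median was -0.36 for smooth muscle and pericytes (camera adjusted p = 0.0024, and adjusted p = 0.67 with an estimated correlation), where 12 of 14 members were lower and 4 passed adjusted over the list alone. Actg2 -2.53, Des -1.60 and Myh11 -1.09 were its largest values. For MAPK feedback and output, 17 of 19 members were lower, with a median of -0.77 (camera adjusted p = 0.0024, and adjusted p = 0.67 with an estimated correlation). Ereg -2.12, Fosl1 -1.68 and Hbegf -1.67 were the largest values, and 0 passed adjusted over the list alone. Matrix collagens and proteoglycans had 15 of 19 members lower and a median of -0.45 (camera adjusted p = 0.003, and adjusted p = 0.67 with an estimated correlation), with Col12a1 -1.23, Vcan -0.89 and Col6a3 -0.78. Adjusted over the list alone, 6 were called lower and 1 higher. The median was -0.39 for hypoxia and glycolysis (camera adjusted p = 0.0041, and adjusted p = 0.67 with an estimated correlation), where 23 of 26 members were lower and 0 passed adjusted over the list alone. Car9 -1.01, Pfkfb3 -0.97 and Slc2a1 -0.82 were its largest values. For mesenchymal transition, 13 of 17 members were lower, with a median of -0.51 (camera adjusted p = 0.0081, and adjusted p = 0.67 with an estimated correlation). Itga5 -1.50, Prrx1 -1.26 and Snai1 -0.84 were the largest values, and 2 passed adjusted over the list alone. DNA replication and S phase had 21 of 26 members lower and a median of -0.32 (camera adjusted p = 0.0081, and adjusted p = 0.67 with an estimated correlation), with Pole -0.69, Mcm4 -0.52 and Gins1 -0.48 and 0 called adjusted over the list alone. The median was -0.26 for immediate early genes (camera adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation), where 18 of 23 members were lower and 0 passed adjusted over the list alone. Fosb -1.20, Dusp1 -0.96 and Ier3 -0.90 were its largest values. For intestinal epithelium, 11 of 14 members were lower, with a median of -0.39 (camera adjusted p = 0.027, and adjusted p = 0.67 with an estimated correlation). Muc2 -3.94, Alpi -2.38 and Reg4 at least 1.97 lower were the largest values, and 1 passed adjusted over the list alone. Cholesterol and fatty acid synthesis had 17 of 22 members lower and a median of -0.31 (camera adjusted p = 0.028, and adjusted p = 0.67 with an estimated correlation), with Cyp51 -1.04, Sqle -0.83 and Hmgcs1 -0.71 and 0 called adjusted over the list alone. The medians that moved by over 1.5 times, or lost their call, when 1 array was left out follow. Mitosis stood at -0.26 without the array labelled knockout 2. Activated myofibroblasts stood at -0.39 without the array labelled knockout 2. Smooth muscle and pericytes stood at -0.39 without knockout 1 (not called). MAPK feedback and output stood at -1.69 without knockout 1 and -0.12 without the array labelled knockout 2 (not called). Matrix collagens and proteoglycans stood at -0.49 without knockout 1 (not called). Hypoxia and glycolysis stood at -0.62 without knockout 1 and -0.10 without the array labelled knockout 2 (not called). Mesenchymal transition stood at -0.78 without knockout 1 (not called) and -0.23 without the array labelled knockout 2. DNA replication and S phase stood at -0.11 without the array labelled knockout 2 (not called). Immediate early genes stood at -0.27 without knockout 1 (not called). Intestinal epithelium stood at -0.55 without knockout 1 (not called). Cholesterol and fatty acid synthesis stood at -0.55 without knockout 1 (not called) and -0.10 without the array labelled knockout 2 (not called). Genes given as at least a value in this comparison lay below that 30th percentile on both arrays of 1 genotype; they were picked and ordered by the measured difference. With dim genes at their bound the median was 1.27 for islet cells, 0.78 for neutrophils, 0.24 for hepatocytes and -0.42 for mitosis.

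No gene passed with the number of intact Nupr1 alleles in limma (smallest adjusted p = 0.14), with 2705 at an unadjusted p under 0.05. The genes of smallest p, none of which passed, were A2m, Hgf, Depdc1a, Klra17, Nuf2 and Trim30d, with 0.84, 0.68, 0.65, 0.62, 0.61 and 1.03 per intact allele, and Gdpd3, Scarna17, Cdc42bpg, Thsd4, Serpind1 and Mapk13, with -0.84, -0.49, -0.45, -0.45, -0.37 and -0.32. Of these, Depdc1a, Klra17 and Nuf2 lay below the 30th percentile on both knockout arrays, and Depdc1a and Klra17 also on both heterozygous arrays, so their values were not measured exactly. Nupr1 itself had 0.42 per intact allele (adjusted p = 0.42), and without the array labelled knockout 2 it had 0.89 (limma adjusted p = 0.028), with adjusted p from 0.028 to 0.87 over 19 alternatives.

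The fold changes of knockout and heterozygote against the same wild-type arrays correlated at 0.29 across 15610 genes, where unchanged groups simulated against those arrays gave 0.40 ± 0.02 (SD over 100 simulations). The covariance was 0.052 against 0.026 in the simulation, a difference of 0.027. The correlation was -0.02 without knockout 1 and 0.65 without the array labelled knockout 2. The simulated covariance already holds the part from the shared wild-type arrays, under the settings of the simulation. Those settings took genes as independent and gave every genotype the same spread, unlike the data. The 3 wild-type arrays could not be split into groups of at least 2. These values therefore cannot decide whether knockout and heterozygous arrays changed alike.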

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

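All tests of the explanations below were chosen after the results they bear on had been seen.

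Probe sets that the annotation used here does not name were left out of the comparisons above, and some of them differed between genotypes. In heterozygotes against wild type 10 of 12146 passed in limma (9 higher and 1 lower), and in knockout against heterozygote 6 passed, all lower; in knockout against wild type 0 passed, with 1641 at an unadjusted p under 0.05.

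The array labelled knockout 2 stood apart from the other 6, and its Nupr1 signal was at the wild-type level. Uneven normalization stays open, because quantile normalization moved its highest correlation with another array only from 0.871 to 0.873 and the lowest among the others stayed at 0.925, so that this test could exclude nothing. More acinar and islet tissue in that sample is consistent with part of its values: all 25 acinar genes were higher than in knockout 1, with a median difference of 2.66, and the islet median was 2.06 higher, while ductal genes lay 0.99 lower (a difference of -0.99), but mesothelial (median 1.40, quartiles -0.03 and 2.38) and neutrophil genes (1.05, -0.21 and 1.92) also lay higher and MAPK genes lower (-1.31, -1.96 and -0.72), which such tissue was not shown to bring. A wrong genotype label stays open: neighbours of Nupr1 that followed the allele number in the other 6 arrays gave a median of 1.02 intact alleles for this array, with quartiles of -0.35 and 1.61. Single genes read both ways, from -0.67 (Cln3) and -0.48 (Gdpd3, the largest change per allele), as the label says, to 2.09 (Coro1a) and 2.37 (Gsg1l), and the same reading gave 0.82 for knockout 1, so the test had little power; signal from exons outside the deletion was not tested.

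The heterozygous arrays were nearly identical, with an SD of the difference of 0.127 over all genes against 0.285 to 0.695 for the other pairs of the same genotype. Hybridisation of 1 RNA on both arrays is argued against, since 24 of 25 acinar genes were higher in heterozygote 1, by a median of 1.18. Whether both arrays came from pieces of 1 tumour cannot be told apart from similar tumours, because no pair here is known to share a tumour. Counted as 1 sample, they left 0 called genes in heterozygotes against wild type.

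The mitosis, macrophage and matrix lists were lower in both knockout arrays. Dilution by acinar tissue may account for part of this in the array labelled knockout 2. Ductal genes also lay below the wild-type mean there (median -0.43, quartiles -0.98 and 0.24). Activated myofibroblast (-1.21) and T and NK cell genes (-0.47) lay below it too. Fibroblast (0.03), endothelial (0.39) and epithelial junction genes (0.72) did not. Wild type 1 had a ductal median of -0.69 with an acinar median of -1.28, so a low ductal median alone does not mark acinar tissue. In knockout 1 ductal genes lay above the wild-type mean (median 0.68, quartiles 0.42 and 1.02), which argues against dilution in that array. This evidence is weak, because wild type 1 (-0.69) lowered the mean, and wild types 2 and 3 stood at 0.27 and 0.42. The arrays with Y-linked signal stay open. Without them the medians of the 3 lists were -0.54, -0.96 and -0.54, but knockout 1 is then the lone knockout array. Calls with an estimated correlation could not decide this. With all arrays, too, none of the 3 lists was called that way (camera adjusted p = 0.58, 0.35 and 0.26). Nupr1 genotype stays open as an untested explanation, as do differences between individual tumours, which 2 knockout arrays cannot separate from genotype.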

How the results depend on the processing

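Leaving out arrays with Y-linked signal, the heterozygous arrays as 1 sample, the acinar covariate and the crossed block were chosen after seeing the data; the other alternatives were fixed before the data were examined. Of the single genes and lists under each alternative, 5505 gene values and 2476 list values kept their direction and side of the threshold, 429 and 91 newly passed, 110 and 201 no longer passed, and 3 and 38 reversed. A further 107 gene values and 142 list values changed direction without a call in either fit; they are counted here and not as reversed. The cause of the changes below was not tested except where stated. The number of called lists was 12 to 24 under the other alternatives. With an estimated correlation it was 0 in each of the 3 comparisons, and fry called 5, 1 and 2 (knockout against wild type, heterozygote against wild type, knockout against heterozygote). Gene counts in the same order were 3, 32 and 0 with the stricter filter, which tests fewer genes. In knockout against wild type they were 6 with quantile normalization, 8 with median centring and 2 without the variance trend. In heterozygote against wild type they were 12 with robust estimation, 583 with only the genotypes compared and 4095 with array weights, an estimation that stopped before convergence. In knockout against heterozygote they were 7 without a filter, 1 with quantile normalization, 5 with median centring, 1 without the trend, 1 with array weights and 0 with only the genotypes compared; array weights gave 1406 genes for the allele number.

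Deviations of samples with the same replicate number correlated at -0.22 to 0.06, so no pairing by replicate number was seen. This check cannot exclude a pairing. In a group of 2 arrays the deviations from the mean mirror each other, and no values for unpaired samples were computed beside them. With the replicate number as a block, 0 genes were called in heterozygote against wild type and 0 in knockout against heterozygote, and with the knockout numbers crossed 1 was called in knockout against heterozygote.

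Leaving out each array in turn gave 0 to 5478 genes in knockout against wild type, 0 to 596 in heterozygote against wild type, 0 to 5712 in knockout against heterozygote and 0 to 1 for the allele number. A lone knockout or heterozygous array is then assumed to vary like the other genotypes. Nupr1 in knockout against wild type ran from -1.80 to 0.235, and the correlation of fold changes from -0.019 to 0.65. In knockout against wild type list medians ran from -0.17 to 1.94 for islet cells, -0.0024 to 1.33 for mesothelial cells, -0.97 to 0.31 for MAPK feedback and output, -0.10 to 0.63 for endoplasmic reticulum chaperones, -0.40 to 0.12 for the type I interferon response and -0.46 to 0.20 for hypoxia and glycolysis. For fibroblasts in knockout against heterozygote they ran from -0.16 to 0.63.

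Without both arrays with Y-linked signal 1225, 2713 and 92 genes were called in the 3 comparisons, Nupr1 stood at -1.81 in knockout against wild type and -0.96 in knockout against heterozygote, and the correlation of fold changes was 0.68. Knockout 1 is then the lone knockout array, and the spread comes only from the heterozygous pair and from wild types 2 and 3. The SD of the difference was 0.127 and 0.285 in those pairs, against 0.695 between the knockout arrays. The larger counts therefore cannot be told from this smaller spread and do not show more genotype effects. Without both arrays with Y-linked signal, Iapp stood at -1.72 and Pparg at 0.45. The list medians that turned in knockout against wild type were -0.42 (islet), -0.50 (endothelial), 0.045 (mesothelial, by its test), 0.37 (MAPK), -0.10 (endoplasmic reticulum) and 0.40 (hypoxia), and in knockout against heterozygote 0.23 (ductal) and -0.16 (fibroblasts). With the heterozygous arrays as 1 sample, 0 genes were called in both comparisons that use them.

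With the acinar mean as a covariate, which takes much of its spread from the array labelled knockout 2, 1 gene was called in heterozygote against wild type and 0 in knockout against heterozygote, and 12 lists in heterozygote against wild type. The lists that turned in knockout against wild type had medians of -0.43 (islet), -0.34 (neutrophils), -0.54 (endothelial), 0.37 (MAPK), -0.080 (endoplasmic reticulum) and 0.42 (hypoxia). The acinar list itself is held near 0 by this covariate, so its values say nothing. In heterozygote against wild type its median of -0.0081 kept its sign, and it is counted above as reversed by its direction in camera. Its 2 other values are counted as no longer passing. The lists that turned in knockout against heterozygote had -0.70 (islet), -0.27 (fibroblasts), -0.62 (inflammatory fibroblast genes), -0.28 (neutrophils), -0.65 (T and NK) and -0.47 (B and plasma). Others were -0.46 (dendritic), -0.41 (endothelial), -0.70 (epithelial junctions), 0.10 (S phase), 0.11 (mitosis) and 0.44 (MAPK). The rest were -0.16 (endoplasmic reticulum), -0.40 (type I interferon) and 0.26 (hypoxia). ATF4 and CHOP targets turned in camera only, as their median of 0.032 kept its sign. The design is limited by 2 or 3 arrays per genotype, and detection above background was not analysed here.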

Other observations

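The genes named in this paragraph and the tests on the neighbours of Nupr1 were chosen after the values had been seen. Without the array labelled knockout 2, 17 genes differed between knockout 1 and wild type in limma, with knockout 1 as a lone array assumed to vary like the other genotypes. Those lower in knockout 1 include the myeloid genes Itgam (-1.64) and Lyz2 (-0.98), the fibroblast genes Pdgfra (-1.002), Islr (-1.25) and Aspn (-1.40), and Trim30d (by at least 2.26, as it was dim in knockout 1) and Nupr1 (-1.80). The array labelled knockout 2 was not the same for all of them. Itgam stood there at 10.46, Lyz2 at 13.10, Pdgfra at 10.97, Islr at 11.24 and Aspn at 8.91, nearer to wild type than to knockout 1. Nearer to knockout 1 were Ms4a6c at 10.02 (wild type 11.44 to 11.65), Trim30d at 7.72 (9.19 to 9.51), Gm1966 at 7.91 (9.80 to 9.99), Wif1 at 7.17 (9.33 to 9.49) and Col6a3 at 9.997 (10.87 to 10.90). Chl1 at 9.22 and Lilra6 at 7.55 lay between. Higher in knockout 1 was En1 (1.84), and Ang5, Ppp2r2c and Slc27a6, dim on every wild-type array, were higher by at least 2.16, 1.20 and 1.03.

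Gdpd3 had the smallest p of 15610 genes in the allele model, with a value of 9.43 and 9.80 in the knockout arrays, 8.64 and 8.75 in heterozygotes and 8.12, 7.91 and 7.78 in wild type, although it did not pass (adjusted p = 0.14; 0.024 to 0.42 over 19 alternatives). It lies 6 tested genes from Nupr1 on chromosome 7. The array labelled knockout 2 thus had a knockout-like Gdpd3 value and a wild-type-like Nupr1 value. A candidate explanation is a stretch of chromosome 7 inherited along with the deleted allele. If that changed many genes of the stretch, more neighbours than elsewhere should follow the allele number: 6 of the 40 nearest tested genes did, against a median of 7 and a 95th percentile of 12 in 378 windows of 40 genes elsewhere. The predicted excess was not seen. The bound first set, a count at or below that median, would have excluded the explanation. It was moved to the 5th percentile (3) after the value had been seen, because a stretch can be inherited and alter few genes, so this test is weak evidence either way. In heterozygotes against wild type, 1 of the 22 tested genes on the list next to Nupr1 passed in limma over all genes, downwards. Sult1a1, 2 tested genes from Nupr1 and picked after its values were seen, stood at 8.41 and 8.50 in heterozygotes. It stood at 9.21 and 9.33 in the knockout arrays and at 9.725, 9.49 and 9.59 in wild type. Sult1a1 thus did not follow the allele number, nor did Il27 and Apobr, 1 and 2 tested genes away. The 6 neighbours that did include Sgf29, 1 tested gene away, and Cln3, 3 away, also picked after their values were seen. Sgf29 stood at 9.26 and 9.31 in the knockout arrays, 9.40 and 9.44 in heterozygotes and 9.57 to 9.75 in wild type. For Cln3 the values were 9.83 and 9.71, 10.05 and 10.03, and 10.14 to 10.35. A stretch that alters few genes stays open, as does a direct effect of the deletion on Gdpd3.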
